A study of Mus musculus with 1094 samples.

How the data were processed

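Single cells of the mouse dorsal cortex were captured and sequenced by the submitters, and the labels give each cell's population and stage. The deposited tables hold TPM, a length-scaled share of the transcripts of a cell, per gene and cell, with 23078 genes and 1094 cells in 17 files, and all columns sum to nearly the same total. TPM were computed with kallisto 0.43.0, per the submitters' processing notes, which name the builds GRCm38.p2 and mm10. The deposited columns of 7 near-empty cells hold only whole numbers, which were named a score and used on the TPM scale. TPM keep no depth, so the depth of each cell is unknown and no read count model was fitted. Precision is described by cells per library (39 to 89), by genes at 1 TPM or more per cell, and by exact binomial intervals at 95% for shares of cells, which cover counting error only.

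Labels name no animals and no batches. What is called a library here is all cells of 1 population at 1 stage, so a difference between captures cannot be told apart from stage within a population. Cells are not replicates. Each library's value was log2 of the mean TPM over its cells plus 1. BP and NBN of a stage may come from the same animals. The p-values then measure the spread between libraries around the fitted type and age effects, which may be technical. The fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. Genes with a mean TPM of 1 or more in at least 4 of 17 libraries were tested, 14072 in all.

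Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The population contrasts used all 17 libraries with age as a covariate. Age trends used a separate slope on age for each population, and the difference of BP and NSC slopes was a contrast of that fit. Age is the embryonic day, and for postnatal cells 18.5 plus the labelled age in days (1 for P0, 2 for P1 and 4 for P3). The mid-course contrast used the 8 NSC libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 read the files and made the shares.

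Lists were fixed before the data were examined: radial glia, basal progenitor, newborn neuron, deep layer, upper layer, synapse, G1/S, G2/M, early stem cell, astroglial, oligodendrocyte, Notch, Wnt, BMP, FGF and SHH, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, DNA methylation and Polycomb, dorsal telencephalon, p53, immediate early, ribosomal protein and mitochondrial genome genes, and markers of interneurons, Cajal-Retzius cells, microglia, endothelial, mural, meningeal, choroid plexus and erythroid cells. Microglial and endothelial markers had too few tested genes for a list test. Lists were tested with camera with a preset correlation of 0.01 and again with an estimated one. Of 240 tests, 100 passed with the preset correlation and 8 with an estimated one: radial glia in BP and in NBN against NSC, astroglial, early stem cell, oligodendrocyte and glycolysis genes with age in NSC, early stem cell genes with age in BP, and astroglial genes in the difference of slopes. The genes named are drawn from the 10 largest rises and falls per contrast among called genes reaching 10 TPM, not all of which are named. Members of the lists were added, and unnamed models were only counted. Members that did not pass and are given with values were chosen after their values were seen, as was the rule for neuron profiles.

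The fit was tested on simulated library values with the real means, noise drawn independently per gene, and 200 changed genes. The noise had each gene's spread around the fit with a separate age slope per population. The population contrasts use a common slope, so differences between slopes add to their real spread. Their shares recovered may therefore be too high. Of changes of 4 log2 units between BP and NSC, 86.4% were recovered, 44.8% of those of 2 and 7.46% of those of 1. Between NBN and BP these were 78.8%, 22.4% and 0%. For NSC slopes of 0.8, 0.4 and 0.2 per day they were 87.9%, 53.7% and 8.96%, for BP slopes 72.7%, 19.4% and 2.99%, and for NBN slopes 27.3%, 1.49% and 0%. Unchanged genes called were 0 to 6 per run. Real genes vary together, so these counts do not give the false calls in the real data. Gene IDs were matched to GENCODE M21 (22361 of 23078 IDs), whose GRCm38 coordinates are given; its release differs from the files' own. Alternatives changed the pseudocount, the filter, the averaging over cells, the scaling, the cells kept, the age term and the libraries. All cells were kept in the main values, 11 of them with under 50 genes. The trend of 1 called gene is not reported here.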

Results

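The developing mouse dorsal cortex was profiled cell by cell across the period in which neural stem cells expand, make neurons and turn to glia. Single cells were captured on microfluidic arrays, and each cell's RNA was sequenced. Neural stem cells (NSC) were sorted by a green fluorescent reporter under the Hes5 promoter, a Notch target. Basal progenitors (BP) and newborn neurons (NBN) came from a reporter under the Tbr2 (Eomes) promoter, a transcription factor of intermediate progenitors. The 1094 cells fall into 17 libraries, each holding 1 population at 1 stage. There are 538 NSC cells in 8 libraries from E10.5 to P1, 344 BP cells in 5 libraries from E12.5 to P0, and the rest are NBN cells in 4 libraries at E16.5, E18.5, P1 and P3. A library holds 39 to 89 cells. The values are TPM, which keep no sequencing depth, so the depth of each cell is unknown. In its place, the median number of genes at 1 TPM or more per cell ran from 3189 in NBN P1 to 5764 in NBN E16.5. The library was the unit of every test, with n = 8 NSC, 5 BP and 4 NBN libraries.

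The first comparison asked how basal progenitors differ from the stem cells they arise from. BP libraries had lower levels of radial glia transcripts. Of 16 radial glia and stem cell genes, 12 were lower in BP and 1 higher when adjusted over the list alone. Over all genes, 10 were lower. They include Hes5 (−3.46 ± 0.60 SE), the stem cell factors Sox2 (−2.50 ± 0.47) and Sox9 (−2.61 ± 0.37), the intermediate filament genes Nes and Vim, the glutamate transporter gene Slc1a3 (−3.63 ± 0.56) and Hes1 (−3.93 ± 0.74), all in log2 units. Hes5 stood at 3.50 ± 1.73 (SD, n = 8) log2(TPM + 1) in NSC and 0.12 ± 0.22 (SD, n = 5) in BP. Hes5 is the gene of the reporter that sorted NSC, so its difference is partly set by the sort. The radial glia list as a whole was lower by limma's camera test (adjusted p = 0.0116 with an estimated correlation). Among called genes reaching 10 TPM, the largest fall was that of Aldoc, a glycolytic enzyme gene of astroglia (chromosome 11, 78322968 to 78327781, GRCm38). Aldoc fell by 7.31 ± 1.13 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00495), from 7.62 ± 3.52 (SD, n = 8) to 0.56 ± 1.23 (SD, n = 5).

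Of 19 astroglial and gliogenic genes, 4 fell in BP (Aldoc, Tnc, Aldh1l1 and Mt3). Adjusted over the list alone, 12 were lower and 1 higher, with camera adjusted p = 0.0789 with an estimated correlation. Others that fell strongly were Id3 (−5.97 ± 1.20), a target of BMP signalling, the matrix genes Sparc (−5.67 ± 0.88) and Cyr61 (−5.40 ± 0.75), the metallothionein genes Mt3 (−5.00 ± 0.57) and Mt1 (−4.60 ± 0.82), the Notch receptor gene Notch2 (−3.82 ± 0.55) and the GABA synthesis gene Gad1 (−3.78 ± 0.65). Mfge8, Acsbg1, Pdpn and Gpx8 lay between −5.00 and −4.60. The 4 genes that rose were the neuronal secretory granule gene Scg2 (3.44 ± 0.58; chromosome 1, 79434669 to 79440120), Cyth1 (2.31 ± 0.49), Zfp112 (3.19 ± 0.57) and Gcg (2.97 ± 0.59). The last pair did not reach 10 TPM and was named after the values were seen. All 14 newborn neuron genes leaned towards BP without a member passing over all genes, 8 of them adjusted over the list alone (adjusted p = 0.206 with an estimated correlation). Examples are Tbr1 (3.01 ± 1.00) and Neurod6 (3.92 ± 1.52). All 19 G2/M genes had negative values, 11 adjusted over the list alone (adjusted p = 0.128 with an estimated correlation), with Plk1 at −3.42 ± 1.01 and Cdk1 at −3.57 ± 1.21. The Cdk1 difference is enlarged by 1 near-empty NSC E11.5 cell of 5 genes, which held Cdk1 at 386230 TPM. Of 12 basal progenitor genes none passed over all genes, and Eomes itself was 0.64 ± 0.96, a direction that turned with stage as a factor (−0.21) and from E16.5 on (−0.31). Nhlh1 (2.95 ± 0.66) passed over the list alone. Gad1 stood with other interneuron genes, all 10 of which had negative values, 5 adjusted over the list alone (adjusted p = 0.0797 with an estimated correlation), and 80 of 538 NSC cells against 8 of 344 BP cells held interneuron markers. Without cells holding markers of another cell type, Gad1 came under the filter and was not tested.

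In all, 67 of 14072 genes differed between BP and NSC (limma, adjusted p under 0.05), 4 higher and 63 lower, with the median of all genes at 0.13. The mean of log2 over cells gave 8 higher and 12 lower, 10 of them in common with the 67. Stage as a factor gave 19 and 58 (24 in common). That fit compares populations only at E16.5, E18.5, P0 and P1, so it rests on far fewer libraries than the main one. Leaving out cells with markers of another cell type gave 3 and 35 (33 in common). Within the NSC libraries, 78 of 86 cells at E15.5 carried more newborn neuron than radial glia transcripts, as described with the cell profiles, and the count was 170 without the E15.5 NSC library. Without NBN P3 it was 26 higher and 119 lower. It was 22 without BP E18.5, 26 without BP P0, 38 without BP E16.5, 41 without BP E14.5, 42 without NSC E10.5 or NSC P0 and 43 without NSC E18.5. Of the 17 fits that left out 1 library, the call was lost in 12 for Vim, 11 for Nes, 10 for Aldh1l1 and 9 for Cyth1.

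**Figure D1:**
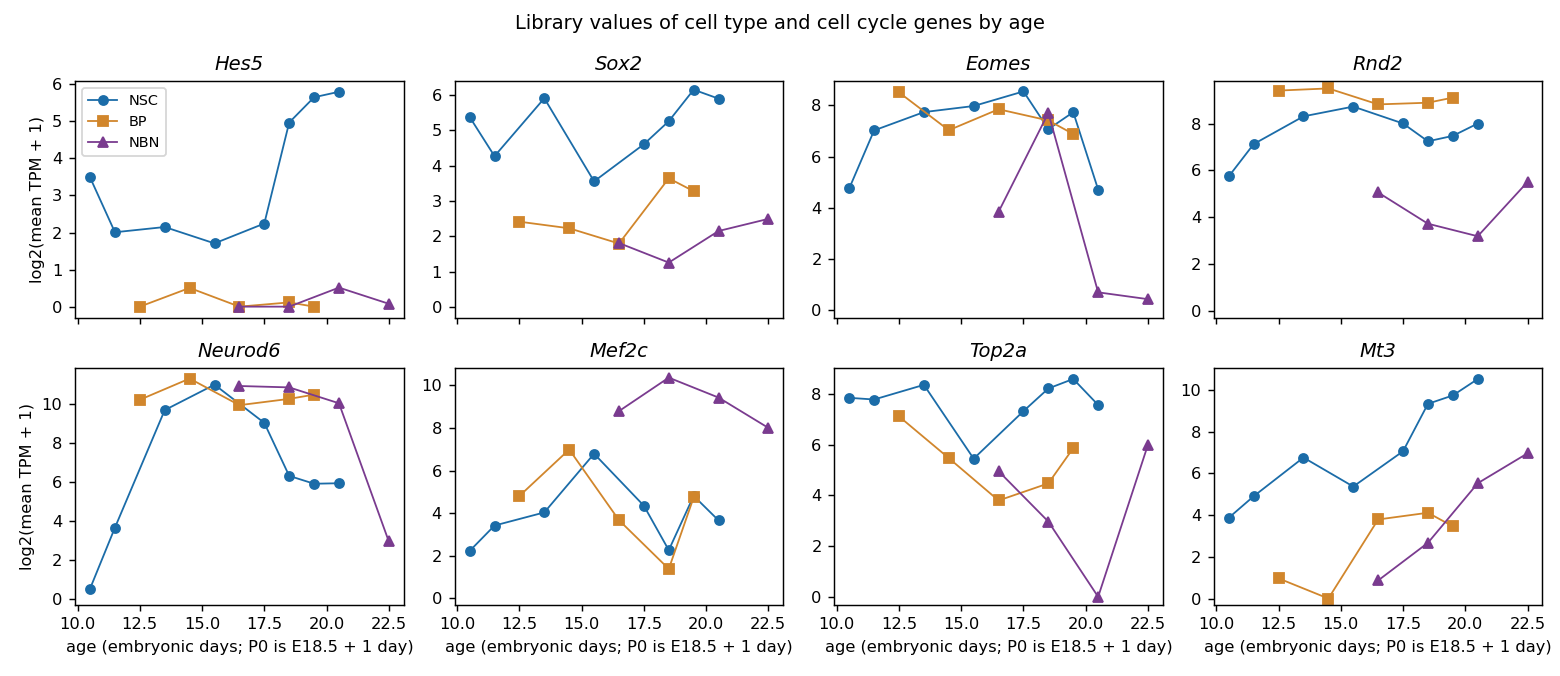
Library values, log2(mean TPM + 1), of 8 genes against age in days (embryonic day, with P0 counted 1 day after E18.5), for NSC (circles), BP (squares) and NBN (triangles); each point is 1 library and lines join libraries of a population in order of age. Hes5, the gene of the NSC sorting reporter, averaged 3.50 in NSC and 0.12 in BP, and Neurod6 in NSC peaked at E15.5, at 2059 TPM.

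The next comparisons asked what newborn neurons lose and gain. Against BP, NBN had less Rnd2, a gene of migrating neurons (−4.98 ± 0.56, limma adjusted p = 0.000327; chromosome 11, 101464999 to 101471853), and less of the long noncoding RNA Rmst (−4.82 ± 0.54, limma adjusted p = 0.000327). These were the 2 of 14072 genes that passed, and 1283 had an unadjusted p under 0.05. With stage as a factor, which sets libraries of a stage against each other, neither passed by limma and 0 genes did, and 1 did from E16.5 on or with a pseudocount of 10. Rnd2 stood at 9.15 ± 0.30 (SD, n = 5) in BP and 4.37 ± 1.09 (SD, n = 4) in NBN. All 12 basal progenitor genes had negative values, 6 adjusted over the list alone, among them Eomes (−3.99 ± 1.21), Sstr2 (−4.64 ± 1.51), Mfap4 (−4.13 ± 1.22) and Nhlh1 (−3.88 ± 0.83), with adjusted p = 0.232 with an estimated correlation. Among upper layer genes, Mef2c (4.97 ± 1.04) and Inhba (3.50 ± 0.93) were higher and Unc5d (−3.25 ± 1.14) lower, adjusted over the list alone. All 5 meningeal fibroblast genes tested were higher adjusted over the list alone (Dcn 5.00 ± 1.17, Col3a1 4.55 ± 1.07), with camera adjusted p = 0.148 with an estimated correlation. Of 40 NBN P3 cells, 13 held meningeal markers. Of 14 newborn neuron genes, 10 had negative values (median −1.13, 0 adjusted over the list alone). That list had a mean of 4.14 log2(TPM + 1) in NBN P3 against 7.39 to 7.99 in the other NBN libraries. NBN P3 thus pulled the NBN side of this list down. All 13 mitochondrial genome genes had positive values, 2 adjusted over the list alone. Neither list passed with an estimated correlation. With quantile normalization 1 gene was higher and 3 lower. With the 2 postnatal NBN libraries left out, a setting chosen after the data were seen, 11 genes passed, 7 higher and 4 lower. With NBN P3 alone left out 15 passed, 14 without NBN P1 and 4 without BP E14.5.

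Against NSC, NBN had lower transcripts of dividing cells. Of 19 G2/M genes, 10 were lower, 19 adjusted over the list alone (adjusted p = 0.0818 with an estimated correlation), among them the topoisomerase gene Top2a (−4.01 ± 0.96), the spindle kinase gene Bub1 (−4.00 ± 0.70), Cenpe (−4.19 ± 0.87) and Mki67 (−3.14 ± 0.74). Among called genes reaching 10 TPM, the largest fall was that of Kif22, a chromosome motor gene (−5.89 ± 0.65, limma adjusted p = 0.000204; chromosome 7, 127027729 to 127042471), and Cdca3, Spc25, Kif23 and the thymidine kinase gene Tk1 lay between −5.71 and −4.64. Rrm2 was the 1 of 19 G1/S and S phase genes to pass (−3.14 ± 0.76), with 14 adjusted over the list alone (camera adjusted p = 0.0884 with an estimated correlation). Leaving out 1 library at a time ended the call of Top2a, Tk1 and Rrm2 in 11 of 17 fits and that of Mki67 in 10. Of 16 radial glia genes, 7 were lower (adjusted p = 0.0269 with an estimated correlation), including Fabp7, the brain lipid binding protein gene (−5.09 ± 0.75), Sox9 (−3.77 ± 0.44), Hes5 (−4.09 ± 0.72), Pax6 (−2.74 ± 0.59) and Notch1 (−3.46 ± 0.60). Of 19 astroglial genes, 5 were lower, with Mt3 at −5.54 ± 0.68 and Bcan at −4.05 ± 0.77 (adjusted p = 0.0818 with an estimated correlation). Of 13 Notch pathway genes, 3 were lower (Notch1, Notch2 and Hes5), with camera adjusted p = 0.0818 with an estimated correlation. Hes5 is again the gene of the NSC sorting reporter.

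Genes higher in NBN than in NSC were led by Sla (6.44 ± 1.44), the dynein gene Dync1i1 (5.40 ± 1.18), the transcription factor gene Mef2c (5.37 ± 0.98; chromosome 13, 83504034 to 83667080), the phosphatase gene Ptpro, the neurotrophin gene Ntf3 (4.79 ± 0.98) and Fam19a2. Mef2c stood at 9.15 ± 1.00 (SD, n = 4) in NBN and 3.95 ± 1.47 (SD, n = 8) in NSC. Of 13 synapse genes, 2 were higher, Camk2b (4.63 ± 1.06) and Syt1 (3.96 ± 0.98), with adjusted p = 0.315 with an estimated correlation. Syt1 lost its call in 13 of the 17 fits that left out 1 library, Fam19a2 in 12, Dcn and Col3a1 in 11 and Camk2b in 6. Of 14 newborn neuron genes 0 passed limma over all genes, 1 adjusted over the list alone. Of 13 mitochondrial genome genes, 2 were higher (mt-Atp8 1.04 ± 0.20 and mt-Atp6), with mitochondrial transcripts at a median of 19.6% of TPM in NBN P1 and 12.7% in NBN P3 against 5.22 to 7.79% in the other libraries. The meningeal genes Dcn (4.52 ± 1.10) and Col3a1 were higher too, with the meningeal cells of NBN P3 in the mean.

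In total, 233 of 14072 genes differed between NBN and NSC (limma, adjusted p under 0.05), 55 higher and 178 lower, and with quantile normalization 111 higher and 163 lower. The balance turned with the mean of log2 over cells, at 159 higher of 264 genes, the others lower (103 in common with the 233), and stage as a factor gave 193 and 216 (126 in common). Without NBN P3, 606 genes passed, 236 higher and 370 lower, 227 of them in common with the 233, and 17 of 19 G2/M genes were lower. Without the 2 postnatal NBN libraries, as chosen after the data were seen, 276 genes passed, 129 in common, and no mitochondrial gene did. The count was 63 without NSC P1, 82 without NSC P0, 98 without NSC E18.5, 121 without NBN E18.5 and 433 without NSC E15.5. Without NBN P1 it was 37 higher and 108 lower.

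The NSC series asked how stem cells change from the expansion to the gliogenic phase. Astroglial genes rose with age in NSC. Of 19, 12 rose and 17 adjusted over the list alone, with all 19 slopes positive (camera adjusted p = 0.000409 with an estimated correlation). Sparcl1, a matrix glycoprotein gene of astrocytes, rose by 1.05 ± 0.10 log2 per day (limma, adjusted p = 0.000109; chromosome 5, 104079111 to 104113733), from 0.254 TPM at E10.5 to 769 TPM at P1. Tnc (0.95 ± 0.10 per day), Aldoc (0.87 ± 0.15), Aldh1l1, a folate enzyme and astrocyte marker (0.82 ± 0.10), Apoe (0.80 ± 0.18), Bcan (0.79 ± 0.12), Gfap (0.69 ± 0.14), Clu (0.66 ± 0.12) and Hopx (0.53 ± 0.12) rose as well. Thrsp, Pla2g7, the thyroid hormone transporter gene Slco1c1, Scrg1 and Ndrg2 rose by 0.81 to 0.96 per day. Of 6 oligodendrocyte lineage genes, 2 rose, Olig2 (0.48 ± 0.11) and Egfr (0.48 ± 0.09), and 5 did adjusted over the list alone (adjusted p = 0.042 with an estimated correlation), among them Olig1 (0.65 ± 0.16) and Pdgfra (0.57 ± 0.16). Within the radial glia list, 4 of 16 rose with age: Slc1a3, Fabp7, Ednrb and Mfge8 (adjusted p = 0.401 with an estimated correlation). Hopx lost its call in 12 of the 17 fits that left out 1 library and Olig2 in 11. These values are means over all cells of a library. Cells with more newborn neuron than radial glia transcripts made up 2.27% at E10.5, 90.7% at E15.5 and 10.6% at P1. A change in the mix of cells was not separated from a change within cells.

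Genes of early stem cells fell. Of 10, 5 fell, 7 adjusted over the list alone, with all 10 slopes negative (adjusted p = 0.00205 with an estimated correlation). Crabp2, a retinoic acid binding protein gene, fell by 0.97 ± 0.19 per day (chromosome 3, 87948666 to 87953376), from 835 TPM at E10.5 to 0.263 TPM at P1, the chromatin protein gene Hmga2 by 0.64 ± 0.11 (547 to 3.51 TPM), the let-7 regulator gene Lin28b by 0.46 ± 0.08, Hmga1 by 0.41 ± 0.07 and the RNA binding protein gene Igf2bp1 by 0.37 ± 0.09. Crabp1, Wfdc2, Rassf7, Sall4, Lsr, Uck2, Nudt8 and Dera fell too, with slopes of −0.75 to −0.51 per day. Of 12 glycolysis genes, 3 fell slowly, Tpi1 by 0.32 ± 0.06, Pkm by 0.26 ± 0.03 and Gapdh by 0.19 ± 0.04, and 8 adjusted over the list alone (adjusted p = 0.042 with an estimated correlation). Of 78 ribosomal protein genes 2 fell (Rps2 by 0.16 ± 0.04 and Rpl10a by 0.13 ± 0.03), 39 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). Of 5 erythroid genes, 4 had negative slopes that passed over the list alone (Hba-a1 −0.68 ± 0.18, Hba-a2 −0.69 ± 0.19; adjusted p = 0.209 with an estimated correlation), and 34 of 59 NSC E11.5 cells held erythroid markers. Gad1 rose by 0.45 ± 0.09, a call lost without any 1 of NSC E10.5, E13.5, P0 or P1, and Gad1 was not tested without cells holding markers of another cell type. Of 10 interneuron genes, 7 had positive slopes, 2 adjusted over the list alone (adjusted p = 0.442 with an estimated correlation), and interneuron markers went up and down, in 1 of 88 NSC cells at E10.5, 15 of 59 at E11.5, 4 of 68 at E13.5, 10 of 86 at E15.5, 19 of 76 at E17.5, 9 of 66 at E18.5, 17 of 48 at P0 and 5 of 47 at P1. The calls of Igf2bp1 and Rpl10a were lost in 14 of the 17 fits that left out 1 library, that of Rps2 in 13 and that of Lsr in 11.

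In NSC, 192 of 14072 genes had a slope on age (limma, adjusted p under 0.05), 158 rising and 34 falling. The mean of log2 over cells gave 262 rising and 1960 falling, 146 of them in common with the 192. The balance of directions thus depends on that choice. The median of genes per cell was 5688 at E10.5, 3428 at E18.5, 5014 at P0 and 3371 at P1. A gene not detected in a cell lowers the mean of log2, so those falls cannot be told apart from lower detection. The count was 85 without NSC E10.5, 96 without P0, 100 without E11.5, 112 without P1 and 124 without E18.5, and 17 without both ends, E10.5 and P1, and 116 without the E11.5 and E15.5 libraries, a setting chosen after the data were seen, with 100 of those in common.

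**Figure D2:**
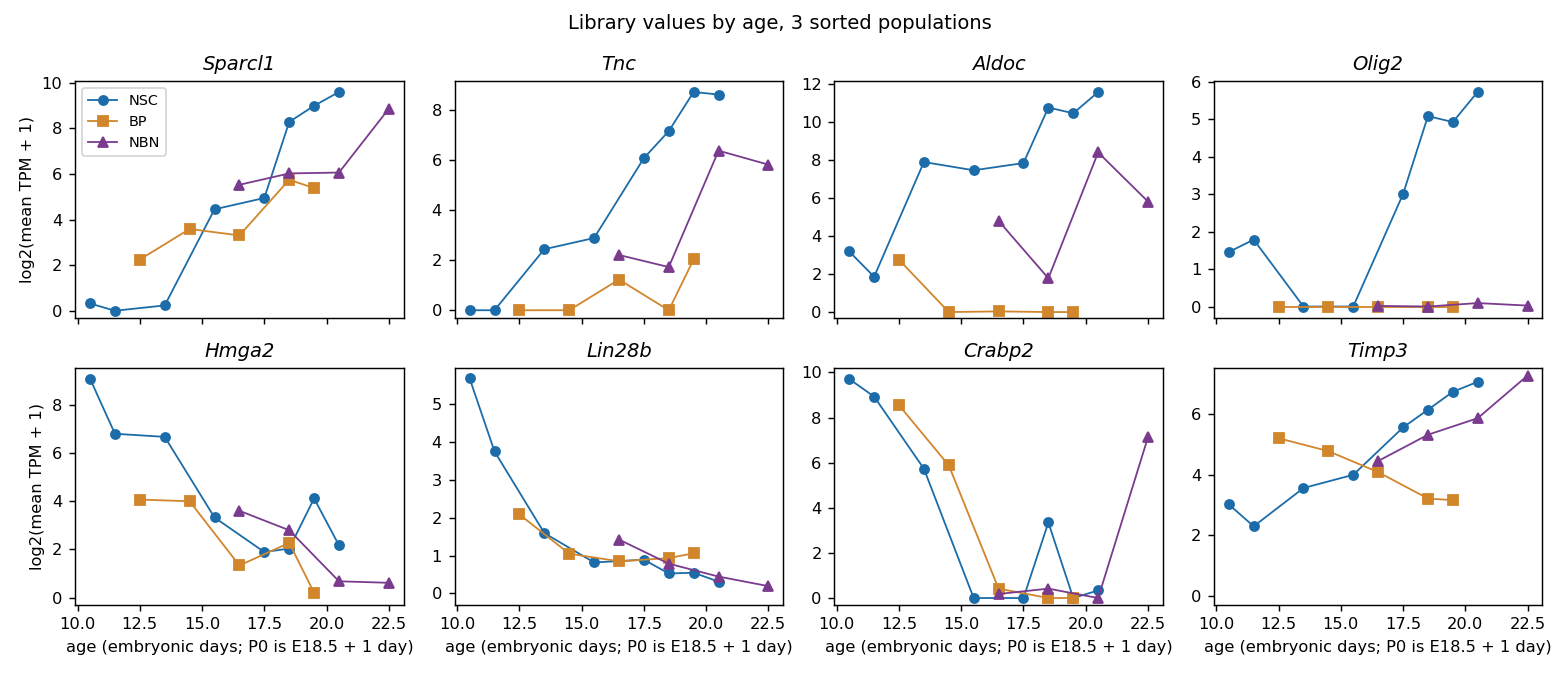
Library values, log2(mean TPM + 1), of 8 genes against age in days (embryonic day, with P0 counted 1 day after E18.5) in NSC (circles), BP (squares) and NBN (triangles); each point is 1 library and lines join the libraries of a population. In NSC, Sparcl1 went from 0.254 TPM at E10.5 to 769 TPM at P1 and Hmga2 from 547 to 3.51 TPM, and Timp3 rose in NSC while its BP values went down.

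In BP, 0 of 14072 genes had an age trend by limma after adjustment (512 at an unadjusted p under 0.05, smallest adjusted p = 0.154). All 10 early stem cell genes had negative slopes in BP, 2 adjusted over the list alone, Crabp2 (−1.31 ± 0.33) and Dmrt3 (−0.60 ± 0.17), and the list passed camera (adjusted p = 0.0449 with an estimated correlation). Of 10 upper layer genes, 3 had positive slopes that passed over the list alone, Pou3f2 (0.56 ± 0.14), Unc5d (0.65 ± 0.23) and Cux2 (0.38 ± 0.13), and 8 of 9 deep layer genes had negative ones (adjusted p = 0.27 with an estimated correlation for either list). Across the 14072 genes, slopes in NSC and BP had a Pearson r of 0.19 and a Spearman correlation of 0.16, over genes that are not independent replicates. Without BP E12.5 the r was 0.11, and it was 0.50 with the mean of log2 over cells. Of the 192 genes called in NSC, 150 had the same sign in BP. The difference of slopes itself passed for 1 gene, the metalloproteinase inhibitor gene Timp3, with a slope of 0.47 ± 0.05 in NSC, −0.32 ± 0.09 in BP and a difference of −0.79 ± 0.11 (limma, adjusted p = 0.0297; chromosome 10, 86300372 to 86349506), and 556 genes had an unadjusted p under 0.05. Its call ended in 13 of the 17 fits that left out 1 library, all but those without NSC E10.5, NSC E15.5, NBN P1 or NBN P3. As a list, astroglial genes had lower slopes in BP than in NSC, with 18 of 19 differences negative (adjusted p = 0.0153 with an estimated correlation), with 4 members passing over the list alone: Aldoc (−1.19 ± 0.30), Aldh1l1 (−0.82 ± 0.19), Tnc (−0.75 ± 0.20) and Sparcl1 (−0.58 ± 0.19).

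In NBN, 63 genes had a slope (limma, adjusted p under 0.05), 16 rising and 47 falling, or 33 and 22 with quantile normalization, with the median slope of all genes at −0.12 per day. Risers were led by the serine synthesis gene Phgdh (1.48 ± 0.22), Slco1c1 (1.32 ± 0.28), the microglial receptor gene Csf1r (1.14 ± 0.22), Fxyd5, Susd3, Mt3 and Sat1. Without NBN P1 and P3 the Csf1r slope was −0.12, a value that rests on NBN E16.5 and E18.5 alone. Fallers were led by Mcts2, Yipf1, Actr6 and Serinc2 (−1.18 ± 0.15). The neuronal kinase gene Cdk5 fell by 1.00 ± 0.16. All 9 deep layer genes had negative slopes, 6 adjusted over the list alone (Ldb2 −1.11 ± 0.40, Tbr1 −0.91 ± 0.36; adjusted p = 0.34 with an estimated correlation). This was not particular to the deep layers, since all 10 upper layer (3 adjusted over the list alone), all 13 synapse (5) and all 14 newborn neuron genes (0) had negative slopes too. Of 13 mitochondrial genome genes, 12 had positive slopes, 1 passing over all genes (mt-Co1, its call lost in 9 of the 17 fits that left out 1 library) and 8 over the list alone (adjusted p = 0.34 with an estimated correlation), with mitochondrial medians of 19.6% of TPM in NBN P1 and 12.7% in NBN P3. In NBN P3, 18 of 40 cells held microglial markers and 27.5% had a neuron profile. Without NBN P3, 1 gene had a slope, and it was not among the 63. The count was 869 without NBN P1, 151 without NBN E16.5, 132 without NSC P1 and 39 without NSC E17.5. It was 10 to 21 without any 1 of NSC E10.5, E11.5, E13.5 or P0, the 5 BP libraries or NBN E18.5. With 1 library left out at a time, Slco1c1 lost its call in 14 of 17 fits, Mt3 in 12, Csf1r in 11 and Fxyd5, Susd3 and Sat1 in 10.

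Stem cells at E13.5 and E15.5, in the neurogenic phase, were set against the mean of earlier and later ones. The transcription factor gene Nfix (4.37 ± 0.48; chromosome 8, 84699876 to 84800344) and Reln, the secreted guidance protein gene of Cajal-Retzius cells (4.31 ± 0.51; chromosome 5, 21884454 to 22344702), were higher, with Cldn20, Lrfn5 and Olfr57. With 2 unnamed gene models these made 7 of 14067 genes (limma, adjusted p under 0.05, smallest 0.0205), none lower, with the median of all genes at 0.19. At an unadjusted p under 0.05 there were 834. The Reln value rested on few cells, at 10 TPM or more in 7 of 68 at E13.5 and 3 of 86 at E15.5. All 14 newborn neuron genes were positive and all 19 G2/M genes negative, with no list passing with an estimated correlation (adjusted p = 0.428 for both), while 52.9% and 90.7% of the cells of these libraries had neuron profiles. No gene passed without any 1 of E17.5, E18.5, P0 or P1. Leaving out E10.5, E11.5, E13.5 or E15.5 left 1 library in the earlier or the middle group. The spread then came from the other groups, so no conclusion is drawn from those counts.

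At E18.5 all 3 populations were collected, with 1 library each and so no test. Sox2 was at 1 TPM or more in 69.7% of NSC cells (46 of 66, exact Clopper-Pearson 95% interval 57.2 to 80.4%), 19.4% of BP cells (10.4 to 31.4%) and 5.71% of NBN cells (1.58 to 14.0%). Eomes was in 28.8% of NSC cells (18.3 to 41.3%), 74.2% of BP cells (61.5 to 84.5%) and 11.4% of NBN cells (5.07 to 21.3%), and the NBN mean of 208 TPM came from few cells, with 2.86% of cells at 10 TPM or more. Neurod6 was in 39.4%, 93.5% and 91.4%, at means of 79.0, 1241 and 1868 TPM. Mki67 was in 36.4% of NSC cells (24.9 to 49.1%), 14.52% of BP cells (6.86 to 25.8%) and 11.4% of NBN cells. At 10 TPM in place of 1, Neurod6 was in 10.6% of NSC cells, Eomes in 48.4% of BP cells and Mki67 in 5.71% of NBN cells. At P0, Eomes was at 1 TPM or more in 60.4% of NSC cells (45.3 to 74.2%) and 53.95% of BP cells (42.1 to 65.45%). Its order at E18.5 thus did not hold there. The intervals cover counting error only.

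The cells of a library differed in profile. By a rule set after the data were seen, a cell was said to have a neuron profile where the mean log2(TPM + 1) of the 14 newborn neuron genes exceeded that of the 16 radial glia genes. This is a range and not a type, with 2 to 16 cells per NSC library within 1 log2 unit of equality. In NSC the share was 2.27% at E10.5, 55.9% at E11.5, 52.9% at E13.5, 90.7% at E15.5 (82.5 to 95.9%), 73.7% at E17.5, 25.8% at E18.5, 4.17% at P0 and 10.6% at P1. It lay between 91.0% and 100% in the 5 BP libraries and between 92.9% and 95.2% in NBN E16.5, E18.5 and P1, and at 27.5% in NBN P3. The rule thus does not tell BP from newborn neurons.

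**Figure D3:**
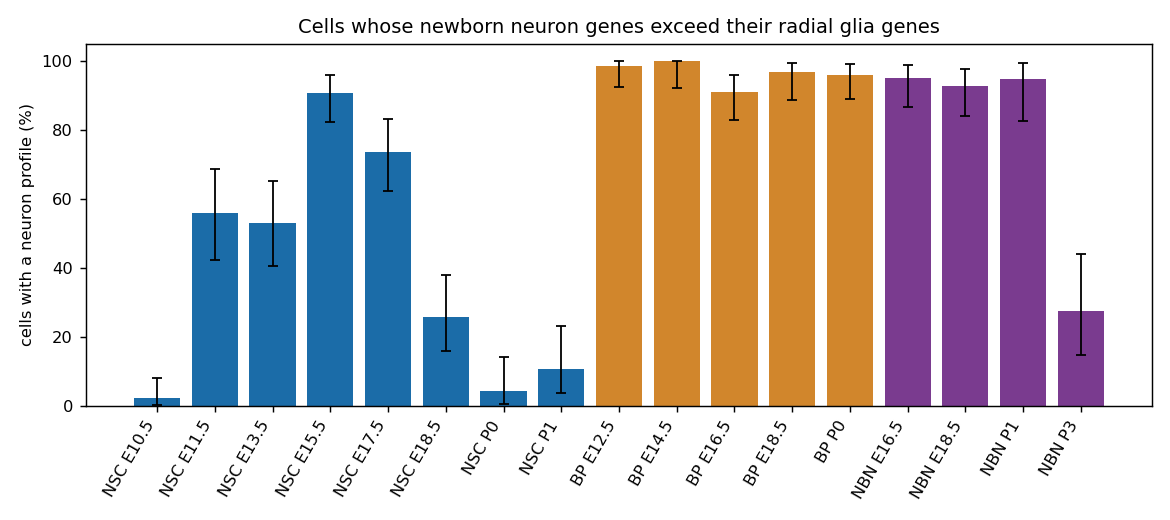
Percent of cells in each of 17 libraries whose newborn neuron genes exceed their radial glia genes on the log2 scale (NSC, BP and NBN from left to right); bars are shares of cells and error bars exact 95% binomial intervals. NSC E15.5 stands at 90.7%, beside BP at 91.0 to 100%, and NBN P3 at 27.5%.

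Markers of other cell types, at least 3 of a list at 10 TPM or more, were found in 210 cells. Interneuron and ventral telencephalon markers were in 80 of 538 NSC cells, up to 19 of 76 at E17.5 and 17 of 48 at P0, against 8 of 344 BP cells. Erythroid markers were in 34 of 59 NSC E11.5 cells and 18 of 88 at E10.5. Cajal-Retzius markers were in 8 of 72 BP E12.5 cells. In NBN P3, 36 of 40 cells held another type's markers: 18 microglial, 13 meningeal, 5 endothelial, 4 interneuron, 3 mural and 1 choroid plexus, some cells holding more than 1 list, with a C1qb mean of 2184 TPM.

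**Figure D4:**
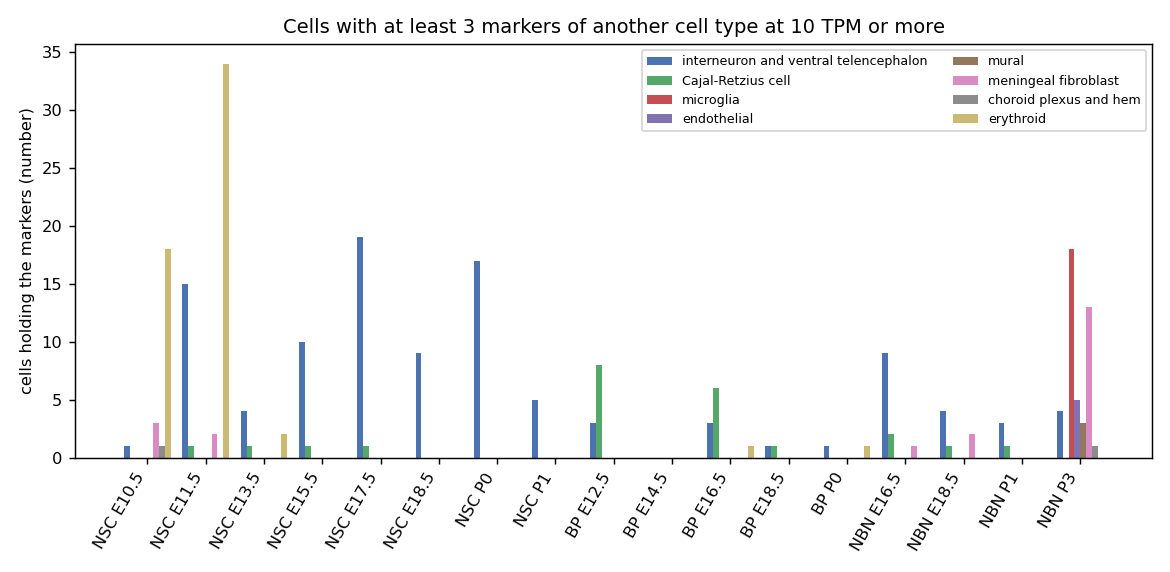
Number of cells in each library with at least 3 markers of another cell type at 10 TPM or more, 1 colour per list; a cell can hold more than 1 list. Erythroid markers peak at 34 cells in NSC E11.5, and microglial markers are in 18 cells of NBN P3 and in no other library.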

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

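The tests of NBN P3, of a mislabelled library, of a BP library under another name and of Y-linked transcripts were chosen only after the result was seen. The regroupings were set before. The test of free RNA was written before its own result. It builds on the neuron profile rule, which was set after the data were seen. Of 87 groups of libraries tested for a value standing apart, 10 gave one, where chance gives about 4.3.

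In NBN P3, 27.5% of cells had a neuron profile against 92.9 to 95.2% in the other NBN libraries, 90% of cells held another type's markers, and the newborn neuron list had a mean of 4.14 log2(TPM + 1) against 7.39 to 7.99. Other values standing apart were the basal progenitor list in BP E12.5 (5.96 against 5.14 to 5.36), the Notch list in NSC P0 (4.56 against 2.87 to 3.25), the BMP list in BP E18.5 (3.25 against 2.57 to 2.72), the FGF and SHH list in NBN P1 (1.95 against 3.17 to 3.23), oxidative phosphorylation in NBN E16.5 (8.39 against 7.98 to 8.03), DNA methylation and Polycomb in NSC E18.5 (4.60 against 4.90 to 5.16) and p53 targets in NSC P1 (2.15 against 2.58 to 2.97). The Timp3 slope differed between BP and NSC by −0.79 log2 per day by a contrast of the slopes.

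The first pattern weighed is the foreign markers of NBN P3. RNA of other cells mixed into neurons, or doublets with a neuron, would leave neuron genes in place, but the 36 marker-holding cells had a median newborn neuron value that differed by −5.61 log2 from that of NBN E18.5 cells (quartiles −6.00 to −4.83). That value argues against both for most of the 36 cells, but a median cannot exclude a minority. In NBN P3, 11 of 40 cells had a neuron profile and 21 lay within 1 log2 unit of equality. The earlier test, in which 12 of 36 cells (18.6 to 51.0%) reached the lowest part of NBN E18.5, did not decide alone. NBN E18.5 itself holds 5 cells without a neuron profile. Of the 36, 29 held the markers of 1 list (80.6%, 64.0 to 91.8%), which is consistent with separate microglial, meningeal, endothelial and mural cells having entered the sort. Why the sort at P3 took them was not tested, and stage and library cannot be told apart for this library.

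The second pattern is the neuron profiles in NSC libraries. A single mislabelled library does not account for it, since the lowest share in E11.5, E13.5 and E17.5 was 52.9% (40.5 to 65.2%). Whether NSC E15.5 is a BP library under another name stays open. Over the 170 genes called between BP and NSC without it, its median place between BP (0) and NSC (1) was 0.385 (quartiles 0.0688 to 0.645). BP libraries placed in the same way stood at −0.219 to 0.140 and BP E12.5 at 0.553, and the other NSC libraries at 0.727 or more. Its nearest library was BP E14.5 (r = 0.885). Against this, Aldoc was at 10 TPM or more in 12.8% of its cells (6.56 to 21.7%) and in at most 1.39% in a BP library (0.0352 to 7.50%). Free RNA from neurons stays open too: neuron genes in cells of radial glia profile stood at 0.107 to 1.69 times their level in neuron profile cells, the highest at E11.5 resting on 1 near-empty cell (0.230 among cells with at least 2000 genes). Carry-over of reporter protein into BP or new neurons may also give such cells and was not measured. The neuron profile does not tell BP from neurons, since 330 of 344 BP cells had it. Cells of NSC libraries with this profile are therefore not shown to be neurons.

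The third pattern is Y-linked transcripts in cells that the labels all call female. At 10 TPM or more, Ddx3y, Eif2s3y, Uty or Kdm5d appeared in 514 of 1094 cells in 15 of 17 libraries, and Xist in 348 cells. Reads shared with X-linked homologues would place them without regard to Xist, but 31 cells held both where 100 would by chance (ratio 0.31). Over all libraries, cells holding both were 8.91% of the Xist cells, as cells of both sexes in 12 libraries would give. The share was higher in NSC P0 (5 of 15 Xist cells), BP E16.5 (7 of 31) and BP P0 (9 of 41), where this reading is less sure. NSC E13.5, NSC E17.5 and BP E14.5 held no Xist cell, and NSC E15.5 and BP E18.5 no Y-linked one. No biological explanation was tested.

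Regrouping the libraries bears on chance. For BP against NSC, 2 of 100 regroupings gave 67 genes or more, the real one included. Such a count was thus uncommon among them. They are a sample of 1287 possible ones, and the libraries differ in age and sex make-up too. The rank alone therefore does not exclude a grouping by other traits. The highest other, 179, put NSC E15.5 in the place of BP E12.5, which points to a structure of the samples. For NBN against NSC it was also 2 of 100, with 233 real and 701 the highest other, which joined NBN P3 with the late NSC libraries. For NBN against BP it was 6 of 100, with 2 real and 5 the highest other, so chance is not excluded. For NSC age, 1 of 100 orders, the real one, gave 192, the highest other giving 65.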

How the results depend on the processing

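No paired analysis was possible because the numbers in the labels name single cells. Stages that populations share were a block in the fit with stage as a factor. Those stages are E16.5, E18.5, P0 and P1. The other libraries, among them NSC from E10.5 to E17.5, added nothing to its population contrasts. Its counts are thus not on the same footing as those of the main fit. Alternatives without the NBN libraries at P1 and P3, or without the NSC libraries at E11.5 and E15.5, were chosen after seeing the data. Stages are 1 day apart except P3, so ranking them changes NBN P3 alone. The named genes kept direction and side of the threshold in 4272 of 5515 comparisons, with 1211 weaker, 27 stronger and 5 reversed. The causes below were not tested.

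For genes differing between BP and NSC (67), the count was 29 with no filter, 20 with the mean of log2 over cells, 38 without cells holding other markers, 41 with 39 cells drawn, 34 with no age covariate, 177 without NBN P1 and P3 and 133 without NSC E11.5 and E15.5; leaving out 1 library gave 22 to 170. For NBN and BP (2), it was 1 with a pseudocount of 10, 4 with mean log2, quantile normalization or no age covariate, 6 without marker cells, 0 with stage as a factor, 1 from E16.5 on and 11 without NBN P1 and P3; leaving out 1 library gave 2 to 15. For NBN and NSC (233), it was 113 with no filter, 1.6e+02 with 39 cells (37 higher and 118 lower), 409 with stage as a factor (193 and 216) and 370 without NSC E11.5 and E15.5; leaving out 1 gave 63 to 606. For NSC age (192), it was 2222 with mean log2 (262 rising and 1960 falling), 118 with 39 cells, 108 with NSC libraries alone, 17 without E10.5 and P1 and 116 without E11.5 and E15.5; leaving out 1 gave 85 to 286. For BP age (0), it was 8 with no filter and 18 with mean log2; leaving out 1 gave 0 each time. For NBN age (63), it was 233 with a pseudocount of 0.1, 780 with no filter, 128 at 10 TPM and 2116 with mean log2. It was 109 with cells of at least 2000 genes and 3182 without marker cells, which leaves 4 cells in NBN P3. With 39 cells it was 0, and 14 with ranked stages or without NSC E11.5 and E15.5. Without NBN P1 and P3 it was 2, but slopes then rest on NBN E16.5 and E18.5 alone, with no NBN spread. Leaving out 1 gave 1 to 869. For the slope difference (1), it was 0 with a pseudocount of 10, mean log2, quantile normalization, without marker cells, with 39 cells or without either pair of libraries, and 3 with no filter; leaving out 1 gave 0 to 1. For the mid-course contrast (7), it was 1 with a pseudocount of 0.1 or at 10 TPM and 38 with no filter. It was 4 without marker cells and 0 with 39 cells. Leaving out any 1 of NSC E17.5, E18.5, P0 or P1 gave 0. Leaving out 1 of all NSC libraries gave 0 to 30, the highest without NSC E13.5. That fit leaves 1 library in the middle group, whose spread then comes from the other groups, so no conclusion is drawn from it. List tests passing went from 100 to 8 with an estimated correlation. The correlation of NSC and BP slopes (0.19) was 0.22 at 10 TPM, 0.50 with mean log2, 0.16 with 39 cells and 0.17 without NSC E11.5 and E15.5; leaving out 1 gave 0.11 to 0.20.

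Reversed values were Bet1 log2 per day in NBN (−0.15) and Clec4a2 log2 per day in NBN (−0.0196) without marker cells. Csf1r log2 per day in NBN was reversed (−0.12) without NBN P1 and P3, where the slope rests on NBN E16.5 and E18.5 alone. Eomes between BP and NSC was reversed with stage as a factor (−0.21) or from E16.5 on (−0.31). At 10 TPM in place of 1, the Eomes share at E18.5 was 48.4% in BP and 2.86% in NBN, and Neurod6 in NSC 10.6%. Depth per cell is unknown and limits what low shares can show. The median of genes per cell was 5688 in NSC E10.5 and 3371 in NSC P1, and 5764 in NBN E16.5 and 3390 in NBN P3. Age trends from the mean of log2 over cells therefore cannot be told apart from a change in detection.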

Other observations

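Few members of the other lists passed over all genes. Of 11 Wnt, 11 BMP, 14 FGF and SHH, 13 cholesterol and fatty acid, 12 oxidative phosphorylation, 12 DNA methylation and Polycomb, 9 dorsal telencephalon, 8 p53 and 10 immediate early genes, those that did in the 8 contrasts were Id3 in BP against NSC, Tcf7l2, Id1, Gli3, Fgfr3, Mdm2 and Pax6, all lower in NBN than NSC, and Spry4, which rose with age in NSC (0.61 ± 0.13). None of these lists passed camera with an estimated correlation. Of 4 choroid plexus and 3 mural genes, 0 passed limma. Among 8 Cajal-Retzius genes Reln was the 1 called, in the mid-course contrast. Olig2 was lower in NBN than in NSC (−3.85 ± 0.82). Fgfr3 lost its call in 12 of the 17 fits that left out 1 library, and Tcf7l2 and Id3 in 8.

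Some transcripts were widespread. Gad2 was at 1 TPM or more in 53.2 to 93.7% of the cells of each library and at 10 TPM or more in 0 to 25.8%. It was in 93.7% in NBN E16.5, at a mean of 9.94 TPM, while Gad1, the other GABA synthesis gene, had a mean of 0.022 TPM there and was at 1 TPM or more in none of the 63 cells, a count that allows a share of up to 4.76% taken as 3 cells of 63, or 5.69% by the exact interval. Pax6 was at 1 TPM or more in 91.4 to 100% of the cells of each library and at 10 TPM or more in 53.2 to 100%, at means of 15.1 to 477 TPM. A threshold of 1 TPM therefore does not separate cells for these genes. Hbb-y, an embryonic globin gene, was in 76.3% of NSC E11.5 cells and was listed at 0 in every NSC library from E15.5 on and in every BP and NBN library.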
